A study of Danio rerio with 6 samples.

How the data were processed

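The RNA-seq data came from livers of zebrafish (Danio rerio) at 7 days post fertilisation (dpf), with 3 libraries labelled sibling and 3 labelled as carrying a mutation of mrpl13, a gene for a protein of the large subunit of the mitochondrial ribosome. Total RNA had been extracted with TRIzol and libraries made with a VAHTS Universal RNA-seq kit, per the labels' protocols. The allele, the sex, the number of animals per library and whether libraries came from separate pools are not given in the sources used here, so p-values measure only the spread between these libraries, which can be technical.

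The deposited table held FPKM (fragments per kilobase of gene and sequencing depth) made by the authors, with each library scaled to its own depth. Per the submitters' processing notes, genome build GRCz11 was used and DESeq2 and R 3.2.0 were among the tools. The aligner, the counting tool, the strand setting and the annotation release are not given in the sources used here. Because FPKM is a share of each library, a large loss of a few abundant transcripts raises the values of all others. The column sums of FPKM ran from 728593 to 834530. From the steps between low values of the same genes, the libraries' relative depth ran from 1 in sibling 1 to 1.131 in mutant 3. The absolute depth is unknown, so no counting interval or detection floor was computed and no count-based test was run.

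The table held 24872 genes (22906 protein-coding and 1966 non-coding) under NCBI gene numbers with symbols, each above 0 in at least 1 library. Of these numbers, 22664 were found in a RefSeq gene table of assembly GRCz12tu, which was used for names only. No coordinates are given, since that assembly is not the build of the deposited values. Symbols that a spreadsheet had turned into dates (14 genes) were restored from the gene number.

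Genes with a mean FPKM of at least 1 over the 6 libraries were tested (10928 genes). Values were taken as log2(FPKM + 1), which understates the fold change of low genes, and tested two-sided with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation with an intensity trend). The fit had group as its only term, and p-values had Benjamini-Hochberg (BH) adjustment over the genes tested, with a threshold of 0.05. All adjusted p-values of genes are from this limma fit. Fold changes are mutant minus sibling on the log2(FPKM + 1) scale, with standard errors (SE). Means of FPKM are given with the SD over 3 libraries. Single values such as mrpl13 were also given a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

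Gene lists for pathways, complexes and cell types were written from textbook knowledge. Of these, 41 had at least 5 tested members (29 pathway lists and 12 lists for other cell types). Complex II subunits (4 tested members) and lymphocyte markers (1 tested member) were not tested. Members of the cytosolic ribosomal list were taken by symbol, leaving out ribosomal protein kinases and similarly named genes. Each list was tested with limma's camera with a preset inter-gene correlation of 0.01 and again with an estimated correlation, with BH adjustment over the lists. Members past the threshold were counted with BH adjustment over all genes tested and with BH adjusted over the list alone. The pathway annotation in the deposited table (KEGG names, 142 pathways with at least 10 tested members) was tested in the same way.

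The genes named in the text follow a rule. It takes mrpl13, then the 10 largest rises and 10 largest falls past the threshold with no overlap between groups, a mean FPKM of at least 5 in the higher group and a descriptive symbol. It adds the 5 genes per direction with the largest difference of mean FPKM and up to 4 members per list with the smallest p. Genes named outside it are said to be so, and some genes that the rule takes are not reported here. Group assignment, tests, lists, naming rule and the alternatives below other than the last 2 were fixed before the data were examined. The matching of list members to older or newer symbols, the exclusion of kinases from the ribosomal list and the pathway tests were set afterwards.

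Sibling and mutant libraries share replicate numbers in the labels, which do not say what a number stands for. Deviations of log2 values from the group means correlated across genes within each number (r = 0.366, 0.399 and 0.481 for numbers 1, 2 and 3). Correlations between different numbers were negative, which centring on group means partly forces. Genes are not independent replicates, and this pairing comes from the data alone. A fit with the replicate number as a block was run as an alternative and is given beside a result where it changed a call or moved a count by more than 1.5 times.

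The other alternatives were a pseudocount of 0.1, no filter on low values, a minimum mean FPKM of 5, rescaling by median ratios, quantile normalization, moderation without a trend or with robust weights, and leaving out each library. After the data had been seen, a fit without sibling 1 and mutant 2 (the library with the most pancreas RNA in each group) and a rescaling that ignored the 20 most abundant genes were added. The procedure was tested on simulated data of the comparison of mutant with sibling, with 200 of 10928 genes changed. It recovered 2% of genes changed by 1 on the log2 scale and 60% of those changed by 2, and 4.6% of its calls were unchanged genes. The simulated noise was independent between genes and between libraries, and far fewer genes were changed than passed the threshold in the data. These percentages therefore need not hold for the data. Plots were drawn with matplotlib 3.10.9.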

Results

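Transcript levels were measured by RNA-seq in 6 zebrafish liver libraries at 7 dpf, 3 labelled as mrpl13 mutants and 3 labelled as siblings. The comparison asks how the liver transcriptome differs when a protein of the mitochondrial ribosome, which translates the messenger RNAs of the mitochondrial genome, carries a mutation. Libraries are named by group label and replicate number (sibling 1 to 3, mutant 1 to 3). Values are the deposited FPKM, whose relative depth differed by at most 1.131 times between libraries while the absolute depth is unknown. Across genes, log2 values of the libraries labelled mutant correlated with each other at r = 0.958 to 0.980. Siblings 2 and 3 correlated at 0.951 and sibling 1 with either of them at 0.862 to 0.865, against 0.744 to 0.821 between groups.

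The transcript of mrpl13 (NCBI gene number 553555) was higher in the libraries labelled mutant. Its FPKM was 20.9, 16.0 and 11.5 in siblings 1 to 3 and 77.4, 67.2 and 67.8 in mutants 1 to 3. The means were 16.1 ± 4.7 and 70.8 ± 5.69 (SD, n = 3 each), a ratio of 4.4 (log2 fold change 2.11, SE 0.278, limma BH-adjusted p = 0.00146). An exact permutation test of the 6 values gave p = 0.1, the smallest it can give. The labels do not give the allele, and a mutation need not lower its transcript, so this value does not check the labels. All directions given here are those between libraries labelled mutant and libraries labelled sibling.

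In the libraries labelled mutant, transcripts of mitochondrial ribosomal proteins, of most nuclear-encoded respiratory chain subunits as scaled by the authors, and of most members of the integrated stress response list were higher. Transcripts of hepatocyte plasma proteins and of complement and coagulation factors were mostly lower. Of 10928 genes tested with limma, 3804 passed the threshold, 3041 of them higher and 763 lower in the libraries labelled mutant. At least a 2-fold change was seen for 3306 of them (2638 higher, 668 lower). The values of the groups did not overlap for 5402 genes (49.4%, where chance gives 10%). The median log2 fold change of all genes tested was 0.37. List medians in the paragraphs of this part are therefore given as differences from that value. Those in the figures and in the additional observations are not. After rescaling by median ratios the median of all genes was 0.02 and the split was 1754 higher to 1222 lower, 58.9% higher in place of 79.9%. With 1 library left out, 2403 genes passed without mutant 2 (1884 higher) and 2027 without mutant 3 (1628 higher, 399 lower, 2027 at least 2-fold). Without mutant 1, 477 genes were lower.

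Nuclear genes of the mitochondrial ribosome rose almost throughout. Of 78 members other than mrpl13, 74 rose and 0 fell over all genes tested, and 76 rose adjusted over the list alone. The list's median lay 1.3 above that of all genes on the log2 scale, and 60 of the 78 had a smaller fold change than mrpl13. The largest rises among those named were mrpl47 (log2 fold change 2.79, SE 0.247), mrps35 (2.75, SE 0.231) and mrpl38 (2.53, SE 0.229). Together the list took 0.14% to 0.17% of the summed FPKM in the siblings and 0.48% to 0.52% in the libraries labelled mutant. With camera the list had an adjusted p = 8.75e-17, and an adjusted p = 0.244 with an estimated correlation. After rescaling by median ratios 54 members rose.

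Nuclear-encoded subunits of the respiratory chain and enzymes of the tricarboxylic acid cycle were also mostly higher as scaled by the authors. Complex I passes electrons from NADH to ubiquinone. Of 38 genes in its list, 34 rose and 0 fell (37 rose adjusted over the list alone), among them ndufs7 (2.39, SE 0.324) and ndufs4 (1.99, SE 0.267). The list also holds ndufa4, counted as risen, and ndufa4l, which may not belong to complex I. Of 30 genes in the list of complexes III and IV, which also holds the carrier cytochrome c, 22 rose and 2 fell (23 and 3 adjusted over the list alone). The electron carrier cycsb rose by 3.93 (SE 0.215) and the complex IV subunit cox6b1 by 2.69 (SE 0.261), while cox6a2 fell by 2.41 (SE 0.304; named after its value was seen). The list of complex V, the ATP synthase, had 20 genes, which include its inhibitory factors beside its subunits. Of these 18 rose (19 adjusted over the list alone), with atp5h at 1.78 (SE 0.288) and atp5d at 1.58 (SE 0.265). Of 25 cycle enzymes, 18 rose and 0 fell (19 and 1 adjusted over the list alone; 1 fell with the replicate block and 3 without sibling 1), with mdh2, malate dehydrogenase, at 2.03 (SE 0.280). Of 35 factors of mitochondrial DNA upkeep and translation, 17 rose (17 adjusted over the list alone), including the elongation factor tufm (2.05, SE 0.248) and the RNA-binding protein lrpprc (2.30, SE 0.326). The ADP/ATP carrier slc25a5 had the second largest gain of FPKM, from 4837 ± 912 to 9479 ± 366 (SD, n = 3 each, limma adjusted p = 0.00929), and was not past the threshold after rescaling by median ratios (adjusted p = 0.243), scaling without the most abundant genes (0.0984), with no filter on low values (0.0909) or without mutant 3 (0.0559).

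With camera, the adjusted p-values of these lists were 1.43e-07 for complex I, 0.00141 for complexes III and IV, 9.76e-05 for complex V, 9.61e-04 for the cycle and 0.0167 for the translation factors. In the same order the values were adjusted p = 0.642, adjusted p = 0.651, adjusted p = 0.642, adjusted p = 0.642 and adjusted p = 0.733 with an estimated correlation. After rescaling by median ratios, 11 members rose for complex I, 12 for complexes III and IV and 5 for complex V. With the same rescaling 9 cycle enzymes and 10 translation factors rose. Without mutant 3, 18 members rose for complex I, 11 for complex V and 7 among the translation factors. The translation factors came to 7 without mutant 2, and complexes III and IV to 14 without mutant 1.

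**Figure D1:**
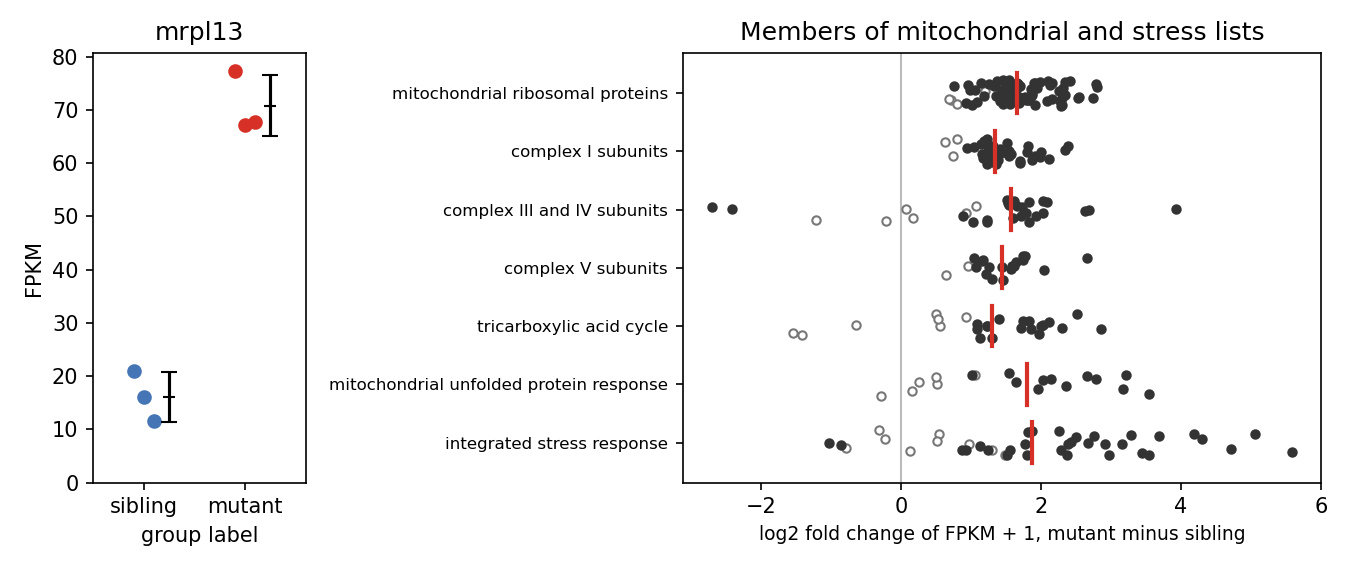
Left, FPKM of mrpl13 in each library (points) with the mean and SD of 3 libraries (black bars). Right, log2 fold change of FPKM + 1 (mutant minus sibling) of each member of 7 lists, filled where limma's BH-adjusted p over all genes tested passed 0.05, with the list median in red, so that 74 of 78 mitochondrial ribosomal members are filled and all of these lie above 0 as scaled by the authors.

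The 13 protein-coding genes of the mitochondrial genome did not move together. ATP6 and ATP8, which code for subunits of complex V and overlap in the genome so that their reads cannot be fully separated, rose by 2.14 (SE 0.458, limma adjusted p = 0.0101) and 2.17 (SE 0.226, adjusted p = 6.19e-04). ND4L rose by 1.17 (SE 0.226), but was not past the threshold after rescaling by median ratios (adjusted p = 0.13), quantile normalization (0.0616) or scaling without the most abundant genes (0.0515). ND1 stood at 1.17 (SE 0.417, adjusted p = 0.0636), and passed with the replicate number as a block (adjusted p = 0.00906), after quantile normalization (0.011), without sibling 1 (0.00168) and without sibling 1 and mutant 2 (0.00408). COX1, COX2 and COX3, subunits of complex IV, stood at -0.47 (SE 0.344), -0.70 (SE 0.412) and -0.42 (SE 0.433), none past the threshold (named after their values were seen), and COX3 stood at 0.09 without sibling 1. After quantile normalization COX1 stood at 0.00 and COX3 at 0.45. The ratio of ATP6 to COX3 within a library, chosen after their values were seen, was 0.78, 0.96 and 0.61 in the siblings. In the libraries labelled mutant it was 4.62, 3.95 and 5.13 (exact permutation p = 0.1, the smallest possible with n = 3 each). As a list, 3 of 13 genes rose (3 adjusted over the list alone), 5 with the replicate block and 9 without sibling 1. The overlapping ATP6 and ATP8 are counted separately in this list. The camera adjusted p was 0.585, with 0.0252 without sibling 1 and 0.00525 without sibling 1 and mutant 2, and with all libraries adjusted p = 0.858 with an estimated correlation. Transcripts of these 13 genes took 17.6% of the summed FPKM in sibling 1, 6.5% and 6.7% in siblings 2 and 3, and 11.5% to 16.3% in the libraries labelled mutant. ATP6 was not past the threshold when genes of low value were also tested (adjusted p = 0.0701).

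**Figure D2:**
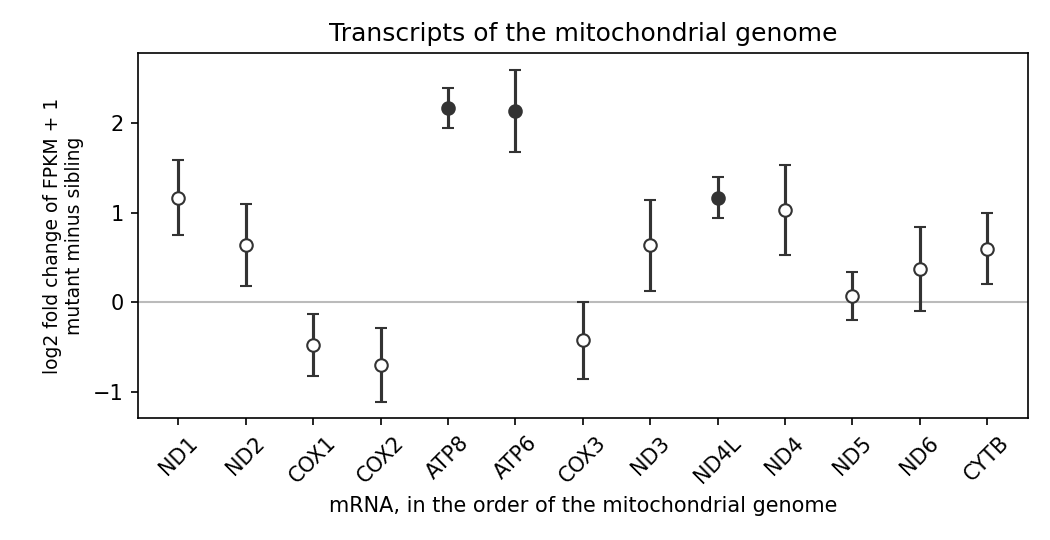
Log2 fold change of FPKM + 1 (mutant minus sibling, n = 3 each) of the 13 protein-coding genes of the mitochondrial genome in genome order, with bars of 1 SE. Filled points (ATP8, ATP6 and ND4L) passed limma's BH-adjusted threshold as scaled by the authors.

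Genes of 2 stress responses were higher. Of 41 members of the integrated stress response list, 30 rose and 2 fell, both over all genes tested and adjusted over the list alone. The list's median lay 1.5 above that of all genes. With 1 library left out, the count that fell ran from 0 (without mutant 1 or mutant 3) to 3 (without sibling 1). The enzymes of serine synthesis psat1 and phgdh rose by 5.59 (SE 0.355) and 4.71 (SE 0.370), the mitochondrial folate enzyme mthfd1l by 4.19 (SE 0.296) and sesn2 by 3.69 (SE 0.271). The neutral amino acid transporter slc1a4 rose from 2.68 ± 3.78 to 142 ± 31.7 FPKM (SD, n = 3 each, limma adjusted p = 7.67e-04). The transcription factor gene atf4a, named after its value was seen, rose by 2.29 (SE 0.328). Of 18 members of the mitochondrial unfolded protein response list, 12 rose and 0 fell (13 rose adjusted over the list alone), including the mitochondrial chaperone genes hspa9 (3.17, SE 0.243), dnaja3b (3.55, SE 0.272) and grpel1 (2.14, SE 0.216), and prohibitin, phb (3.22, SE 0.225). With camera the adjusted p-values were 2.7e-06 and 4.51e-04, or adjusted p = 0.321 and adjusted p = 0.651 with an estimated correlation. After rescaling by median ratios 23 and 8 members rose.

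Of 27 members of the endoplasmic reticulum stress list, 13 rose (13 adjusted over the list alone), led by the chaperone hspa5 (3.14, SE 0.393) and the transcription factor xbp1 (1.72, SE 0.225). Its camera call (adjusted p = 0.0243, and adjusted p = 0.733 with an estimated correlation) ended without sibling 1 (0.131), without mutant 2 (0.0873), without both of these (0.188) and with a minimum mean FPKM of 5 (0.119). Its members that rose came to 7 without mutant 2 or without mutant 3 and to 8 after rescaling by median ratios. Of 45 ribosome biogenesis genes, 36 rose (41 adjusted over the list alone), such as the nucleolar proteins fbl (1.85, SE 0.218) and gar1 (1.97, SE 0.253), with 22 after rescaling by median ratios and 19 without mutant 2 or without mutant 3. Of 84 cytosolic ribosomal protein genes, 65 rose and 1 fell (75 and 1 adjusted over the list alone), among them rps8a (1.34, SE 0.205) and rplp0 (1.12, SE 0.207). After rescaling by median ratios 1 rose and 1 fell, with rps8a at an adjusted p = 0.111 and rplp0 at 0.215 (0.0594 when scaled without the most abundant genes and 0.0502 with no filter on low values), and 21, 29 and 8 rose without mutant 1, 2 and 3. The camera adjusted p-values were 1.48e-07 for biogenesis and 9.8e-08 for the cytosolic proteins, and adjusted p = 0.651 and adjusted p = 0.489 with an estimated correlation.

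Transcripts of proteins that hepatocytes secrete into plasma fell. Of 38 members of the hepatocyte list, 23 fell and 1 rose, both over all genes tested and adjusted over the list alone, and the list's median lay -2.23 from that of all genes. The list took 20.9%, 34.4% and 30.3% of the summed FPKM in siblings 1 to 3 and 5.6% to 6.0% in the libraries labelled mutant. The apolipoproteins apoa1b and apoa2 went from 54170 ± 15200 to 8136 ± 651 FPKM and from 50940 ± 17100 to 7319 ± 1070 FPKM (SD, n = 3 each), with limma adjusted p-values of 4.35e-04 and 5.70e-04. The fetuin genes fetub, ahsg1 and ahsg2 fell, with log2 fold changes of -3.71 (SE 0.227), -6.57 (SE 0.288) and -6.75 (SE 0.472). The inhibitor heavy chain itih3a stood at -5.78 (SE 0.292), serpina1l at -4.20 (SE 0.216) and the retinol carrier rbp4 at -2.96 (SE 0.240). The hepatocyte fatty acid binding protein fabp10a, named after its values were seen, was at 18210, 48347 and 37980 FPKM in the siblings and 19036, 18112 and 20288 in the libraries labelled mutant (log2 fold change -0.75, SE 0.349, limma adjusted p = 0.137). It passed the threshold without sibling 1 (-1.16, adjusted p = 0.00117), without sibling 1 and mutant 2 (0.00387) and when scaled without the most abundant genes (0.0437), and stood at 0.86 after quantile normalization.

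Of 46 complement and coagulation genes, 27 fell and 1 rose (31 and 2 adjusted over the list alone; 2 rose with the replicate block or without sibling 1), among them complement component c3a.3 (-3.44, SE 0.276), cfhl3 (-3.33, SE 0.248) and the coagulation factor f7i (-3.76, SE 0.298). The hepatocyte and complement lists each had a camera adjusted p = 1.15e-18, and adjusted p = 0.244 with an estimated correlation. After rescaling by median ratios 23 and 28 members fell. Without sibling 1 and mutant 2, the library of each group with the most pancreas RNA, all 23 hepatocyte members that fell remained past the threshold.

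Among 37 genes of xenobiotic metabolism, 18 fell and 4 rose (19 and 6 adjusted over the list alone; 2 rose after rescaling by median ratios and 1 without mutant 3; camera adjusted p = 4.56e-10, and adjusted p = 0.321 with an estimated correlation). The cytochrome P450 genes cyp2ad2, cyp2n13 and cyp1a fell (-6.42, SE 0.449, -5.48, SE 0.329, and -4.46, SE 0.397), whereas cyp2aa11, of the same superfamily, rose from 4.53 ± 0.983 to 470 ± 77.3 FPKM (SD, n = 3 each, limma adjusted p = 1.22e-04). Of 20 bile acid genes, 7 fell and 1 rose, both over all genes tested and adjusted over the list alone. The count that rose was 0 after rescaling by median ratios and without sibling 2, sibling 3, mutant 2 or mutant 3. The gene cyp7a1, which codes for the rate-limiting enzyme of bile acid synthesis, fell from 277 ± 153 to 4.79 ± 2.1 FPKM. The sterol hydroxylase family member cyp27a7 fell by 3.14 (SE 0.323). The bile acid list had a camera adjusted p = 7.4e-04, and adjusted p = 0.489 with an estimated correlation. Of 44 genes of amino acid and urea metabolism, 14 fell and 5 rose (16 and 5 adjusted over the list alone), with tdo2a, tryptophan dioxygenase, at -2.52 (SE 0.238). The glutamine synthetase gene glula fell by 2.96 (SE 0.253) while its paralog glulb rose by 3.54 (SE 0.328). That list's camera adjusted p was 1.23e-05, and adjusted p = 0.642 with an estimated correlation, and 9, 7 and 9 members fell without sibling 3, mutant 2 and mutant 3, while 3 and 2 rose without mutant 1 and mutant 3 and 2 after rescaling by median ratios.

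Glycolytic genes moved both ways. Of 33 members, 16 rose and 5 fell (16 and 6 adjusted over the list alone; 3 fell without mutant 1), and the camera adjusted p was 0.27. The liver glucokinase gck fell from 76.8 ± 21.5 to 1.19 ± 1.57 FPKM and the glucose transporter slc2a2 by a log2 fold change of -3.54 (SE 0.291). The enolase eno1a rose from 7.77 ± 5.16 to 544 ± 5.5 FPKM, the phosphofructokinase pfkpa from 2.09 ± 1.95 to 135 ± 10.9 FPKM, and the aldolases aldocb and aldoaa by 5.80 (SE 0.332) and 3.00 (SE 0.268). Of 22 genes of gluconeogenesis and glycogen, 3 fell and 2 rose, both over all genes tested and adjusted over the list alone (5 fell with the replicate block or after rescaling by median ratios and 9 without sibling 1), including fbp1b (-2.54, SE 0.363) and the glucose 6-phosphatase g6pca.2 (-1.60, SE 0.277). Its camera call (adjusted p = 0.0167, and adjusted p = 0.643 with an estimated correlation) ended after rescaling by median ratios (0.0621), without sibling 3 (0.0653) and without mutant 2 (0.0572).

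**Figure D3:**
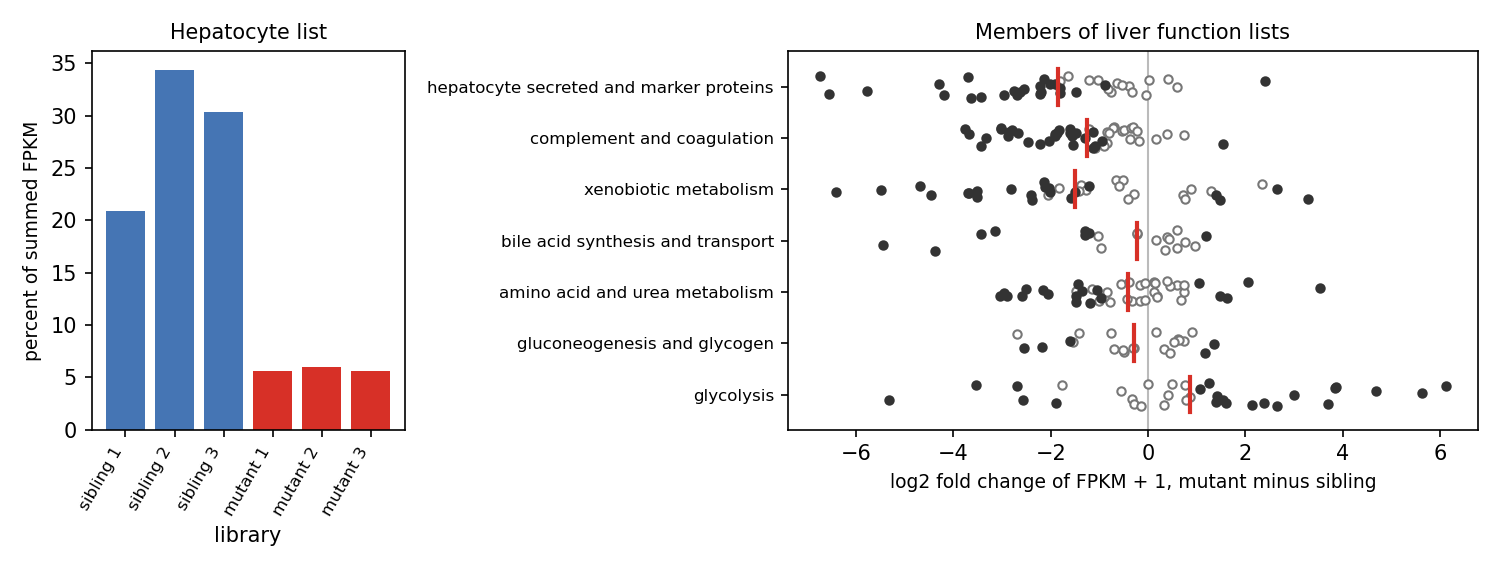
Left, percent of each library's summed FPKM taken by the hepatocyte list, 20.9% to 34.4% in siblings and 5.6% to 6.0% in libraries labelled mutant. Right, log2 fold change of FPKM + 1 (mutant minus sibling) of each member of 7 lists, filled where limma's BH-adjusted p over all genes tested passed 0.05, with list medians in red.

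Among single genes, the largest rises that the naming rule took and that are not given above were s100a1, from 0.745 ± 0.654 to 238 ± 29.6 FPKM, ociad2 (log2 fold change 6.24, SE 0.774), the neurofilament gene nefma (6.01, SE 0.315) and the calmodulin gene calm1b (5.53, SE 0.401). The largest falls not given above were cbln8, from 154 ± 71.9 to 0.339 ± 0.0876 FPKM, comtd1, from 131 ± 61.9 to 0.203 ± 0.139 FPKM, and slc2a9l2 (-5.53, SE 0.379). By difference of mean FPKM, the beta-actin gene actb2 rose from 1891 ± 490 to 6531 ± 275 FPKM and the galectin lgals2b from 1193 ± 450 to 5227 ± 419 FPKM (SD, n = 3 each). Each of these genes was past limma's adjusted threshold with no overlap between the groups.

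Markers of neighbouring cell types differed between libraries within each group. The mean log2(FPKM + 1) of 22 exocrine pancreas genes was 8.65, 6.73 and 3.78 in siblings 1 to 3 and 5.00, 6.81 and 1.94 in mutants 1 to 3. The chymotrypsinogen gene ctrb1, an abundant member named after its values were seen, ran from 98.6 to 3711 FPKM in the siblings and from 23.4 to 1606 FPKM in the libraries labelled mutant (log2 fold change -1.34, SE 1.71, and 0.37 without mutant 3). Of these genes 1 rose and 1 fell (0 and 0 adjusted over the list alone), and 12 fell with the replicate block and 4 without sibling 3. The amylase gene amy2a stood at -3.97 (SE 1.01), past the threshold (adjusted p = 0.0192) but not without mutant 1 (0.0548), without mutant 3 (0.06) or with no filter on low values (0.0669). Of 24 intestine markers 2 rose and 3 fell (2 and 2 adjusted over the list alone; 7 fell with the replicate block, 1 without mutant 3), and of 23 endothelial markers 0 rose and 1 fell (0 and 0 adjusted over the list alone; 0 fell with the replicate block or with any 1 library left out and 6 after rescaling by median ratios). The camera adjusted p-values were 4.32e-04 for pancreas, 0.00161 for intestine and 0.00161 for endothelium, all lower, and adjusted p = 0.733, adjusted p = 0.733 and adjusted p = 0.720 with an estimated correlation. The endothelium call ended with a minimum mean FPKM of 5 (0.154).

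Cholangiocyte markers, those of the bile ducts, rose for 5 of 18 genes (5 adjusted over the list alone), with krt18 at 2.88 (SE 0.295) and cldn7b at 2.63 (SE 0.330), and macrophage markers for 5 of 12 (5 adjusted over the list alone; 3 after rescaling by median ratios), with tspan36 at 3.40 (SE 0.284). The macrophage count was 9 with the replicate block, 8 without sibling 2 and 3 without mutant 2 or mutant 3, and neither list passed with camera (adjusted p = 0.453 and 0.155), though the macrophage list passed with no filter on low values (0.00727) and stood at adjusted p = 0.733 with an estimated correlation. Skeletal muscle markers had a camera adjusted p = 0.134, and 7.91e-04 without mutant 2 or 0.00122 without sibling 1 and mutant 2 (lower), with a mean log2(FPKM + 1) of 4.54 in mutant 2 against 2.60 and 2.95 in mutants 1 and 3. With all libraries that list had an adjusted p = 0.753 with an estimated correlation. In all, 21 of 41 lists passed with the preset correlation and 0 with an estimated correlation, where camera adjusted p-values ran from 0.244 to 0.858. Other splits of the 6 libraries gave 13 to 25 lists with the preset correlation.

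**Figure D4:**
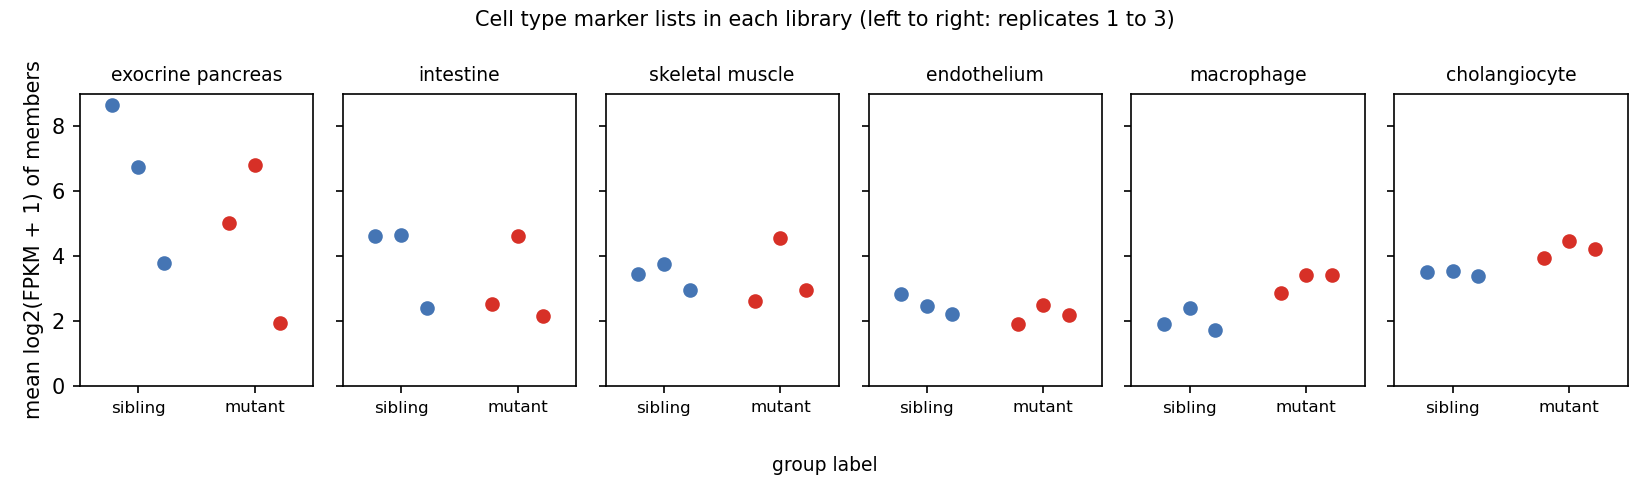
Mean log2(FPKM + 1) of the members of 6 cell type lists in each library, with replicates 1 to 3 from left to right within each group. Exocrine pancreas markers spread from 3.78 to 8.65 among siblings and from 1.94 to 6.81 among libraries labelled mutant.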

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

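The fits without sibling 1 and mutant 2 and without the most abundant genes were chosen after the results had been seen. The count of higher and lower genes depended on the scaling. Against 3041 higher and 763 lower as deposited, median ratios gave 1754 and 1222, quantile normalization 1890 and 1326, and scaling without the most abundant genes 1662 and 1161, and 2512 genes were past the threshold both as deposited and with median ratios. With 1 library left out, genes past the threshold ran from 2027 (without mutant 3) to 4705 (without sibling 1), higher genes from 1628 to 3680, lower genes from 399 to 1025 and those with at least a 2-fold change from 2027 to 3720. Cell type lists past the threshold ran from 3 to 5 with 1 library left out, the highest without mutant 2, and came to 5 without sibling 1 and mutant 2. With an estimated correlation 0 lists passed, of all lists and of the cell type lists (0). The estimated value lay above the preset 0.01 for most lists, such as 0.096 for mitochondrial ribosomal proteins and 0.883 for exocrine pancreas, but 0.005 for glycolysis. A higher correlation makes camera's test of a list stricter. It cannot account for all of the lost calls. In the pathway annotation, tyrosine metabolism (estimated correlation -0.018) and pantothenate and CoA biosynthesis (-0.004) lay below the preset value and lost theirs too. Each went from a camera adjusted p = 5.22e-05 to 0.342 with the estimated correlation. What else accounts for the lost calls was not tested, so these losses do not by themselves show correlated members. With the replicate block 4446 genes passed in place of 3804. The block brought the cell cycle list (adjusted p = 0.111 without it and 0.00304 with it) and ND1 past the threshold, as some other alternatives did, and it changed no other call of a list or named gene. Of 89 named genes past the threshold, 83 stayed past it in each alternative and 0 changed sign. Most of these genes were named for large changes or small p-values in the same data, so their stability does not extend to the other calls. Of all 3804 calls, 2024 were also past the threshold without mutant 3. Among named genes not past it, signs turned for COX1 (0.004) and COX3 (0.449) and fabp10a (0.856) with quantile normalization, for COX3 without sibling 1 and mutant 2 (0.211), and with 1 library left out for COX3 (from -0.737 to 0.087) and ctrb1 (from -2.703 to 0.371), and the cause was not tested. The absolute depth is unknown, so values of low genes carry an unknown counting error.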

Other observations

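The pathway tests, the paralog comparisons and the tests of explanations in this part were chosen after the results had been seen. Genes of the proteasome and of aminoacyl-tRNA biosynthesis were mostly higher in the libraries labelled mutant. In the pathway annotation of the deposited table, 40 of 45 tested proteasome genes rose and 0 fell by limma (42 adjusted over the list alone, 30 after rescaling by median ratios). Of 40 genes of aminoacyl-tRNA biosynthesis, 32 rose and 0 fell (34 adjusted over the list alone, 26 and 1 after rescaling). Named after their values were seen, the tRNA synthetase genes kars, yars and gars rose from 89.9 ± 19.5 to 1999 ± 143, from 11.9 ± 0.417 to 347 ± 53.4 and from 37.5 ± 11.1 to 335 ± 35.7 FPKM (SD, n = 3 each). Of 137 spliceosome genes 70 rose and 0 fell (79 adjusted over the list alone), with 39 and 1 after rescaling, 1 falling with the replicate block, 42 without mutant 2 and 40 without mutant 3. Of 142 pathways, 37 passed with camera's preset correlation (13 higher and 24 lower) and 0 with an estimated correlation. Among the lower ones, 8 of 18 genes of primary bile acid biosynthesis fell and 0 rose (9 adjusted over the list alone; 4 without mutant 3; adjusted p = 5.21e-06, and adjusted p = 0.969 with an estimated correlation). The 3 higher pathways above stood at adjusted p = 3.98e-10, 4.84e-09 and 9.95e-05, and each at adjusted p = 0.969 with an estimated correlation.

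The other lists gave mixed counts. Of 25 p53 target and apoptosis genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone), including casp9 (1.89, SE 0.231), baxa (2.26, SE 0.285) and bbc3 (1.66, SE 0.297), with 7 and 6 rising without mutant 2 and mutant 3 and 1 falling without mutant 1 or without mutant 3. That list's camera adjusted p was 0.332, and 0.046 with no filter on low values, and adjusted p = 0.733 with an estimated correlation. Of 37 antioxidant genes, 13 rose and 6 fell (15 and 6 adjusted over the list alone), including the thioredoxin txn (3.72, SE 0.242) and the peroxiredoxin prdx1 (2.75, SE 0.3), and the count that fell was 3 without sibling 2, mutant 1 or mutant 2. The antioxidant, interferon and hypoxia lists did not pass with camera (adjusted p = 0.5, 0.408 and 0.751). The interferon-induced gene isg15 rose by 5.33 (SE 0.487), with 6 of 13 members of its list rising (6 adjusted over the list alone; 3 without mutant 2, without mutant 3 or after rescaling by median ratios), and the hypoxia list had 6 rising and 2 falling of 22 (6 and 2 adjusted over the list alone; 5 falling without sibling 1 and 0 without mutant 1 or without mutant 2), led by pfkfb3 (4.69, SE 0.563). Of 44 autophagy and lysosome genes 18 rose and 2 fell (20 and 2 adjusted over the list alone), with 6 and 4 after rescaling by median ratios, 9 rising without mutant 2, 5 rising without mutant 3 and 5 falling without sibling 1. Its camera adjusted p was 0.265, and 0.0231 with no filter on low values, and adjusted p = 0.733 with an estimated correlation. Among 31 genes of fatty acid synthesis and storage 6 rose and 5 fell (6 and 5 adjusted over the list alone; 3, 3 and 2 fell without mutant 1, 2 and 3), where the desaturase scd rose (3.69, SE 0.471) and the desaturase fads2 fell (-4.97, SE 0.735). Among 38 of fatty acid oxidation 7 rose and 4 fell (6 and 4 adjusted over the list alone), and the count that rose was 12 with the replicate block, 1 after rescaling by median ratios and 12 without sibling 2, 3 without sibling 3, and 1, 2 and 0 without mutant 1, 2 and 3. The count that fell was 8 without sibling 1 and 1 without mutant 3. Both fatty acid lists had medians above 0 while camera, which compares with all other genes, placed them lower (adjusted p = 0.137 and 0.189, past the threshold at 0.0161 and 0.0126 without sibling 1 and at 0.0171 and 0.042 without sibling 1 and mutant 2), as it did for neutrophil, stellate and epidermis markers (adjusted p = 0.455, 0.5 and 0.291). With all libraries the fatty acid lists had adjusted p = 0.733 and adjusted p = 0.783 with an estimated correlation. Of 34 cell cycle genes 3 rose (1 adjusted over the list alone), among them ccnd1 (1.81, SE 0.288), against 17 with the replicate block, 18 without sibling 2 and 1 without mutant 1, without mutant 2 or without mutant 3. Its camera adjusted p was 0.111, and it passed with the replicate block (0.00304), median ratios (0.0122), quantile normalization (0.025), no filter on low values (0.0145) and scaling without the most abundant genes (0.0253), and without sibling 2 (1.71e-04) or mutant 3 (0.0225), but stood at adjusted p = 0.783 with an estimated correlation. Cholesterol synthesis had 1 of 26 rising and 1 falling (0 and 1 adjusted over the list alone; 3 and 4 with the replicate block; 4 rising without sibling 2; 4 falling after rescaling by median ratios), and its camera call (adjusted p = 0.0385, and adjusted p = 0.733 with an estimated correlation) ended without sibling 2 (0.689), mutant 1 (0.109) or mutant 3 (0.103), and with median ratios (0.0893), quantile normalization (0.0707), no filter on low values (0.0972) or scaling without the most abundant genes (0.115). Not past the threshold with camera were also acute phase (adjusted p = 0.189, but 0.00717 and lower with a minimum mean FPKM of 5), erythrocyte (0.111, but 0.0492 without sibling 1 and 0.00859 without sibling 1 and mutant 2), endocrine pancreas (0.247, but 0.0289 without mutant 2) and neuron markers (0.751). The first 3 of these had adjusted p = 0.733, adjusted p = 0.733 and adjusted p = 0.770 with an estimated correlation.

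Paralogs moved apart in some families. The glutamine synthetases glula and glulb and the apolipoproteins apoa4b.1 (-2.07, SE 0.427) and apoa4a (4.36, SE 0.551) each had a member that fell and a member that rose. Reads shared between paralogs were not resolved, since the counting method is not given in the sources used here.

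The fall of hepatocyte plasma protein transcripts was weighed against 3 technical explanations. A lower share of hepatocytes in the sample would by itself lower all members alike, apart from low genes, whose fold change is understated. Yet 24 of 38 members had a 95% interval that excluded the list's median of -1.86. Unequal falls speak only against a lower share as the whole account. They leave a large fall common to the members open. Of 12 other cell type lists, 4 had medians above that of all genes, macrophages the highest at 1.11. For pancreas and gut RNA carried over, the test could not decide. The least level such RNA would bring was estimated at 3.58% of the summed FPKM with sibling 1 and 1.87% without it. The pancreas and intestine lists took 0.36%, 1.16% and 0.14% in mutants 1 to 3, against 3.55%, 1.54% and 0.41% in siblings 1 to 3. The values of mutants 1 to 3 lay below both estimates. Mutant 2 was not far enough below the estimate without sibling 1 to decide, under a margin set after the values had been seen. Mutant 3, with the least of these markers, had a hepatocyte share of 5.6%, against 6% in mutant 2. Carried-over RNA without these markers was not tested. Rescaling by median ratios gave a list median of -2.30, and the 23 members that fell all stayed past the threshold. That rescaling divides each library by 1 factor, so with a median of all genes above 0 it had to deepen the fall. Quantile normalization, which does not use 1 factor, gave -2.26. These values argue against the authors' scaling as the source only as far as these alternatives reach. A change of hepatocyte gene expression with the genotype stays open as a hypothesis, and a lower share of hepatocytes may still add to it.

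The rise of ATP6 and ATP8 without one of COX1, COX2 and COX3 was weighed against 2 explanations. A change in the amount of mitochondrial RNA would leave the transcripts of the 13 genes in proportion. Yet relative to their mean within each library, 7 of the 13 differed between the groups by limma, with ATP6 and ATP8 counted separately. Among them were ATP6 at 1.49 and COX2 at -1.34 on the log2 scale (limma adjusted p = 1.18e-04 each). Without sibling 1, the library with the most mitochondrial RNA, 8 of the 13 differed. Centring on the mean partly forces both counts, since the rise of ATP6 and ATP8 lowers the centred values of the others. ND5, for example, stood at -0.573 centred and at 0.075 before centring. A genotype difference in the processing or stability of the mitochondrial transcripts may account for the uneven change and was not tested. The annotation and read sharing behind these genes stay open.

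The higher mrpl13 transcript in the libraries labelled mutant was weighed against 2 explanations. The gene may move with its class, since 76.9% of the 78 other mitochondrial ribosomal protein genes had a smaller fold change, within the range of that class. Exchanged group labels cannot be told apart from the labels as given, because mrpl13 lay 0.44 above the median of its class, the allele is not given and no other value in these libraries names the genotype. Whether the mutation leaves the transcript level untouched was not tested.

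The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past the threshold 1 of the 10 splits gave as many, the real one, with 3804 genes against at most 7 in another split. The same held for higher genes (1 split, 3041 against 0), lower genes (1 split, 763 against 7) and genes with at least a 2-fold change (1 split, 3306 against 7). For lists past the threshold with the preset correlation 3 splits gave as many, with 21 in the real split and 13 to 25 in the others. For cell type lists 8 splits did, with 3 in the real split and 8 in another. Among the 4 splits that part all 3 replicate numbers, the 3 other than the real one gave 0 genes past limma's threshold. Every split other than the real one mixes both groups on each side, so a difference between the groups widens the spread within its sides. Its low count of genes is partly forced by this, and the gap does not measure what grouping at random would give.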
